A study of Homo sapiens with 4 samples.

How the data were processed

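Gene expression was measured by RNA sequencing in 4 libraries of LNCaP cells, 2 transfected with a CRYM expression vector and 2 with an empty vector, per the labels. Cells at passage 22 were kept in medium with 10% serum and received 2500 ng of plasmid with 12 µL of a lipid reagent, and RNA was taken at 48 h, per the labels' protocols. Libraries were made with a stranded mRNA kit and sequenced as single reads of 50 bp, per the labels' protocols. Whether the quantification used the strand is not given in the sources used here. TopHat2 2.1.1, Bowtie2 2.2.9, Cufflinks 2.2.1 and Cuffdiff are named with the builds hg19 and GRCh37, per the submitters' processing notes, without their roles.

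The deposited values are FPKM, fragments per kilobase of transcript scaled to mapped fragments, with a lower and an upper bound and a status for each locus, per the file headers. Each library has its own table. Some loci carry an Ensembl identifier, a symbol and a biotype, and others only a number that the assembler gave separately in each library. The libraries were therefore joined by identical position, where the planned design had assumed a join by gene identifier. A locus was named where at least 1 library lists it under an Ensembl identifier. Of 52318 loci listed in all 4 libraries, 37712 had a name, and 27 identifiers with more than 1 such locus were summed. Of the 2498 tested identifiers, 2094 were found in the table of gene names used as reference, and the symbols printed are those of the files. The 7593 tested loci without a name, CRYM among them, were not matched to genes otherwise, as no annotation of hg19 was used here. The CRYM locus was identified by its neighbours: the files list ANKS4B, this unnamed locus, CTD-2547E10.3 and SNX29P1, and the RefSeq table of GRCh38.p14 lists ANKS4B, CRYM, LOC105371125, ABCA15P and SNX29P1 in that order. Positions are counted from 1.

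FPKM is not a count, so the test was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with 2 groups, empirical Bayes moderation with a trend, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. A log2 difference is on the log2(FPKM + 1) scale, which understates the change of low genes, and a fold is the ratio of mean FPKM. Loci with an FPKM of at least 1 in at least 2 libraries and the status OK in all 4 were tested, 10091 in all, and 45 were left out by status. Gene lists were tested with limma camera at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and with fry beside it. The 29 lists, the settings listed as planned and the rule for named genes were fixed before the data were examined. That rule takes CRYM, KLK3, THRA, THRB and another gene that is not reported here, then the 12 largest rises and 12 largest falls among named loci past the threshold whose groups do not overlap. It also takes up to 4 members past the threshold of each list, or where none passes the 2 highest, and the highest member of each untested list of markers. Because the largest changes were loci at 0, 20 protein-coding rises and 20 falls at loci of at least 300 bp with no library at 0 were added after the values were seen. So were the tests of symbol families and biotypes, for which prefixes without a family meaning were left out by hand, and 4 unnamed loci.

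The depth of each library was compared through the lowest values. At loci of 60, 61 and 62 bp, 100.0% of values above 0 were whole multiples (within 0.02) of what 1 read is worth, and the 3 widths gave the same depth of 1.15, 0.842 and 1.07 relative to empty vector library 1. The absolute depth is unknown. If a deposited interval spans 2 SD of counting error on each side, it implies a number of fragments. Its median at a tested locus was 907.8 to 1139 per library, a relative SD of 2.96% to 3.32%. At some loci the implied number does not follow the FPKM, and the cause was not tested. At some abundant loci it was near the same in every library though the depth differed. Its ratio at equal depth does not show there whether reads changed. The interval covers counting error only.

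The fit was tested on simulated data with the means and spread of the 10091 loci, in which 50 loci changed at each of 4 sizes. It recovered 32% at a log2 change of 0.5, 78% at 1, 90% at 2 and 86% at 3, with 7 false calls among 150. The changed loci were drawn from those with a mean log2(FPKM + 1) over 2, and were far fewer than the 3365 called in the real comparison. These shares therefore do not describe low loci or a comparison with so many calls. Alternatives covered the pseudocount, the filter, the status, 3 scalings, the replicate number as a block, the variance model and each library left out in turn. Subsets of loci were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the join and the tests of explanations.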

Results

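LNCaP is an established human prostate cancer cell line that grew from a lymph node metastasis. The cells were transfected with a vector that expresses CRYM or with an empty vector, and polyadenylated RNA was sequenced 48 h later, with 2 libraries per group. CRYM encodes mu-crystallin, a cytosolic protein that binds thyroid hormone and also acts as a ketimine reductase. The comparison asks which transcripts differ when CRYM is overexpressed. The value for each locus is the FPKM that Cufflinks gave in each library, and 10091 loci were tested. Relative to empty vector library 1, the depth was 1.15 in empty vector library 2, 0.842 in CRYM library 1 and 1.07 in CRYM library 2. The labels call the 2 samples of a group biological replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples only.

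CRYM itself was 64.1-fold higher in the cells given the CRYM vector. Its locus (hg19 chromosome 16, 21250195 to 21314404) had an FPKM of 1.17 and 0.977 in the empty vector libraries, with deposited intervals of 0.872 to 1.48 and 0.724 to 1.23. In the CRYM libraries it had 65.3 and 72.5, with intervals of 62 to 68.7 and 69.2 to 75.7. The group means were 1.08 ± 0.139 and 68.9 ± 5.02 (SD, n = 2 each), a log2 difference of 5.07 (SE 0.0870) with a limma adjusted p of 0.00253. Without any 1 library, in turn empty vector 1, empty vector 2, CRYM 1 and CRYM 2, the log2 difference was 5.0 to 5.15 and the limma adjusted p 0.0550 to 0.0713. The files give this locus no name, and it was taken as CRYM because it is the single unnamed locus between ANKS4B and CTD-2547E10.3, where the order of neighbouring genes places CRYM. It overlaps the ANKS4B locus, whose FPKM stayed below that needed for testing. The fragments implied by the deposited intervals rose 32.5-fold at equal depth, less than the FPKM did. Reads from the vector and from the endogenous gene cannot be separated in these values.

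**Figure D1:**
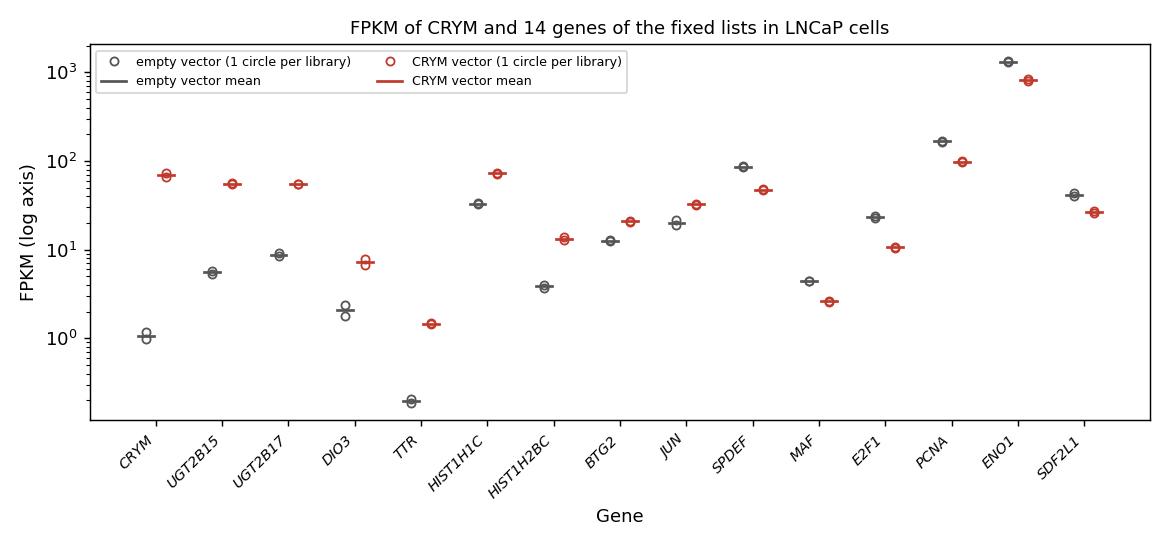
FPKM (log axis) of CRYM and 14 genes of the lists fixed beforehand, in empty vector (grey) and CRYM vector (red) cells; each circle is 1 library and each bar the mean of 2. CRYM went from 1.08 to 68.9, UGT2B15 from 5.53 to 55.7 and E2F1 from 23.3 to 10.6. In every gene drawn both circles of one group lie on the same side of both circles of the other. The 14 genes are only a part of the 37 different tested members of the lists. Among members left out, the groups overlapped in HSPB1 (525.0 and 541.8 against 496.9 and 533.4) and HSPA5 (161.7 and 153.1 against 159.4 and 158.7). The separation therefore depends on which genes were drawn and does not describe the lists.

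Of the lists of genes that androgen regulates, 2 of 29 induced and 2 of 7 repressed members were tested. UGT2B15 and UGT2B17, enzymes that attach glucuronic acid to androgens and that androgen represses, rose 10.1-fold and 6.29-fold. UGT2B15 (chromosome 4, 69512348 to 69536346) went from 5.53 ± 0.270 to 55.7 ± 1.28 FPKM (SD, n = 2) and UGT2B17 (chromosome 4, 69402902 to 69434245) from 8.74 ± 0.459 to 55.0 ± 0.591, with limma adjusted p of 0.00252 and 0.00253. These paralogs are nearly identical in sequence, so how their reads were divided between them is uncertain. SPDEF (chromosome 6, 34505579 to 34524110), a transcription factor of luminal prostate cells, fell 1.81-fold from 85.7 ± 1.66 to 47.4 ± 0.842 FPKM, and the transcription factor MAF fell 1.70-fold from 4.43 ± 0.0318 to 2.60 ± 0.0115, with limma adjusted p of 0.00517 and 0.0113. The fragments implied for SPDEF were 2016 and 2054 in the empty vector libraries and 1712 and 1831 in the CRYM libraries. They did not follow depth between the empty vector libraries, so their ratio at equal depth, 0.985, does not show whether its reads fell. The fragments implied for MAF were at 0.727 of the empty vector level at equal depth, a smaller fall than in FPKM. All 4 genes passed over the tested loci. Adjusted over the list alone, the 2 tested androgen-induced members were lower and the 2 tested androgen-repressed members higher. The files give no name to a locus of KLK3, THRA or THRB in all 4 libraries, and no value is given for them.

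Of the proteins that handle thyroid hormone, DIO3, the deiodinase that inactivates it, rose 3.52-fold from 2.06 ± 0.418 to 7.26 ± 0.885 FPKM (SD, n = 2), with a limma adjusted p of 0.0166. TTR, the transthyretin that carries thyroxine in plasma, rose 7.51-fold from a low 0.195 ± 0.0144 to 1.47 ± 0.0377 FPKM (limma adjusted p = 0.00912), with 9 and 12 implied fragments in the empty vector libraries. These were the 2 tested of the 17 members of that list, and both were also higher adjusted over the list alone. KLF9, a gene that thyroid hormone induces, had 19.9 ± 0.288 FPKM in empty vector cells and 14.9 ± 2.30 in CRYM cells. It did not pass over the tested loci (limma adjusted p = 0.0997) and passed adjusted over the list alone (0.0446), as the 1 tested member of its list. On rescaling to the same total it was called lower. Its implied fragments were 6583 and 7637 in the empty vector libraries and 2066 and 4827 in the CRYM libraries. They did not follow its FPKM between the CRYM libraries, where it had 16.6 and 13.3.

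Of the 20 DNA replication genes of that list only 2 were tested, and both fell, also adjusted over the list alone. E2F1, a transcription factor of the G1 to S transition, fell 2.2-fold from 23.3 ± 0.861 to 10.6 ± 0.331 FPKM (SD, n = 2), and PCNA, the sliding clamp of DNA polymerase, fell 1.69-fold from 166.6 ± 3.50 to 98.4 ± 2.35, with limma adjusted p of 0.00609 and 0.00597. PCNA overlaps the locus of SNORA26. Its implied fragments were 2902 and 2944 in the empty vector libraries and 2644 and 2702 in the CRYM libraries. They did not follow depth, so their ratio at equal depth, 1.04, does not show whether its reads fell. No member of the mitosis list has a name in the joined files. Among the replication-dependent histones 2 of the 3 tested members rose. HIST1H1C went from 33.1 ± 0.537 to 72.3 ± 2.45 FPKM and HIST1H2BC from 3.88 ± 0.211 to 13.2 ± 0.670, while HIST2H2AC had 2.60 ± 0.252 and 1.86 ± 0.178 and did not pass over the tested loci, though it was lower adjusted over the list alone. Many histone genes share near-identical coding sequence, so these values are uncertain, and they cover polyadenylated RNA only. BTG2, an antiproliferative p53 target and the 1 tested member of that list, rose 1.64-fold from 12.6 ± 0.317 to 20.8 ± 0.107 FPKM (limma adjusted p = 0.00676). This call was lost when libraries were rescaled to the same total. The implied fragments of BTG2 rose less than its FPKM, to 1.31 times the empty vector level at equal depth.

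JUN rose 1.60-fold and JUNB fell 1.34-fold among 3 tested immediate early genes. Adjusted over the list alone, the same count passed in each direction. The implied fragments of JUNB, at 0.915 of the empty vector level at equal depth, fell less than its FPKM. Of 6 tested interferon-stimulated genes, IFIT2 rose 1.86-fold, from 0.824 to 1.53 FPKM, and IFI6 fell 1.28-fold, and adjusted over the list alone 1 was higher and 2 were lower. Of 6 tested genes of the unfolded protein and integrated stress responses, SDF2L1 fell 1.56-fold and XBP1 1.17-fold, none rose, and adjusted over the list alone 3 were lower. The implied fragments of XBP1 were 3027 and 3083 in the empty vector libraries and 2765 and 2933 in the CRYM libraries. They did not follow depth, so their ratio at equal depth, 1.06, does not show whether its reads fell. The implied fragments of SDF2L1 were at 0.795 of the empty vector level at equal depth, a smaller fall than in FPKM. The chaperone HSPA5 of that list had 157.4 and 159.1 FPKM. JUN and IFIT2 lost the call on rescaling to the same total, JUNB, XBP1 and IFIT2 with quantile normalization, and JUNB, XBP1, IFIT2 and IFI6 without the filter, and JUNB also without a trend in the variance model. The interferon and stress response lists were the 2 with at least 5 tested members, and neither passed limma camera: the adjusted p was 0.728 for the interferon list and 0.186 for the stress response list, and 0.887 and 0.454 with an estimated correlation. For the interferon list the median log2 difference was -0.06 and the mean 0.04, with camera in the direction of the median. By limma fry, which asks whether the genes of a list move on balance in one direction, the stress response list was lower (adjusted p = 0.0291) and the interferon list was not past (0.861). The limma fry test of change in either direction, which any members can pass, gave an adjusted p of 2.71e-05 for the interferon list and 0.00194 for the stress response list.

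Single members of other lists also passed. ENO1, an enzyme of glycolysis, fell 1.61-fold from 1320 ± 6.31 to 820.1 ± 39.4 FPKM (SD, n = 2). NSDHL of cholesterol synthesis fell 1.29-fold, the luminal marker HOXB13 1.14-fold, and SNAI1, an inducer of the epithelial to mesenchymal transition, 1.72-fold from 1.60 to 0.930 FPKM. Each was also lower adjusted over its list alone. NSDHL, SNAI1 and HOXB13 lost the call without the filter, and HOXB13 also with quantile normalization. ENO1 overlaps ENO1-IT1. The implied fragments of ENO1 were 2325 and 2328 in the empty vector libraries and 2297 and 2312 in the CRYM libraries. Those of HOXB13 were 2218 and 2234, and 2170 and 2210. These numbers were near the same in every library though the depth differed. Their ratio at equal depth, 1.12 for each gene, therefore does not show whether reads changed. TWIST1 of the mesenchymal list had 3.66 and 3.45 FPKM. HSPB1, the 1 tested heat shock gene, had 533.4 and 515.2 FPKM. The ribosomal protein genes RPL27 and RPLP1 had 2145 and 1469 FPKM in empty vector cells and 1952 and 1172 in CRYM cells, and passed adjusted over the list alone but not over the tested loci. Of the markers of other cell types, the immune list had its highest member in HLA-DRA, at 2.35 and 1.76 FPKM without a call. On rescaling to the same total HSPB1, RPL27, RPLP1 and HLA-DRA were called lower. INSM1 of the neuroendocrine list averaged 0.00344 FPKM over the 4 libraries and CLDN5 of the endothelial list 0.214. The basal and fibroblast lists have no named member in the joined files.

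In all, 17 of the 29 lists had tested members, 37 different genes, of which 9 were higher, 12 lower and 16 not past. Of the rest, 4 lists had named members below the level for testing (choline and phosphatidylcholine synthesis, NF-kappaB targets, neuroendocrine and endothelial markers). Another 8 had none named (lysine and pipecolate pathway, mitosis, fatty acid synthesis, hypoxia, NRF2 and NADPH supply, mitochondrially encoded genes, basal and fibroblast markers). RXRB, SLC44A4, HSPA1A, HSPA1B and RPS18 appear under their names only on alternative haplotype sequences, listed at 0, which is no value for the gene.

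Over the 10091 loci, 1582 were higher and 1783 lower in CRYM cells (limma, adjusted p under 0.05), and 4654 had an unadjusted p under 0.05. Of the 2498 with a gene name, 367 were higher and 292 lower, and of the 800 protein-coding ones 139 and 187. At 72.2% of loci the groups did not overlap, where chance gives 33.3% for a single locus. All loci share the same 4 libraries, so any difference between libraries can move many loci together, and the 2 shares do not test an effect of CRYM. The Pearson correlation of log2 values across loci, which are not independent, was 0.941 between the empty vector libraries, 0.915 between the CRYM libraries and 0.902 to 0.908 between groups. With any 1 library left out, in turn empty vector 1, empty vector 2, CRYM 1 and CRYM 2, limma called 0 loci (3627 to 3815 had an unadjusted p under 0.05), and the smallest adjusted p was 0.0550 to 0.0713. Rescaling each library to the same total shifted the median locus by -0.383 and gave 301 higher and 6303 lower, a share of higher calls of 4.6% in place of 47.0%, and testing without a filter gave 788 and 1082.

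**Figure D2:**
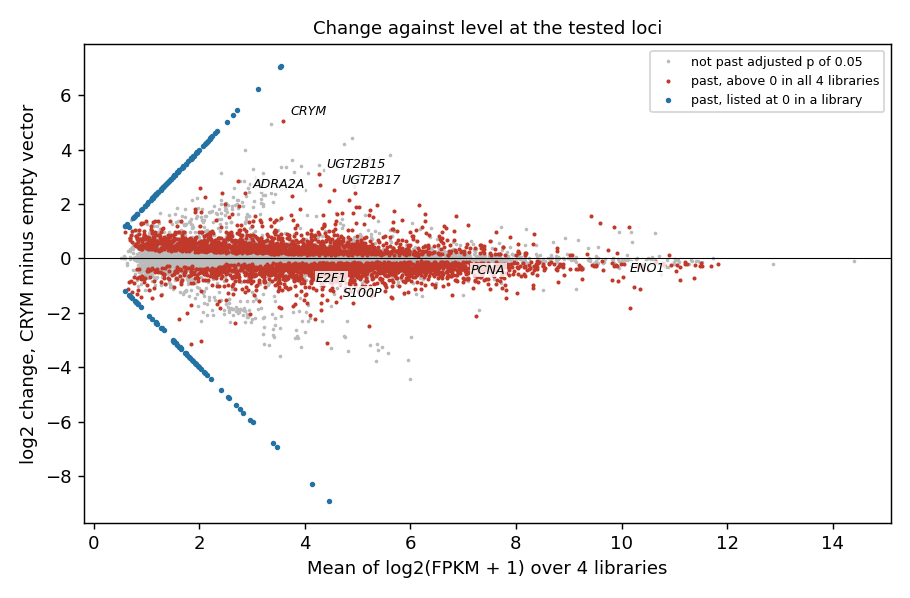
Log2 difference, CRYM minus empty vector, of each tested locus against its mean log2(FPKM + 1) over 4 libraries; grey loci did not pass an adjusted p of 0.05, red ones did and were above 0 in all 4 libraries, and blue ones did and were listed at 0 in at least 1. CRYM lies at 5.07 and UGT2B15 at 3.12, and the blue loci form the 2 outer lines because a value of 0 in one group fixes the difference to the level in the other.

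By the rule fixed beforehand, the 12 largest rises and 12 largest falls among named loci were noncoding RNA and pseudogene loci, and all 24 were listed at 0 in both libraries of one group. RNU7-163P, a U7 small nuclear RNA pseudogene of 63 bp, was listed at 518.8 and 450.7 FPKM in empty vector cells and at 0 in CRYM cells, and SNORD73 at 0 in empty vector cells and at 214.4 and 84.1 in CRYM cells. The deposited intervals imply 1 fragment in each empty vector library for RNU7-163P, and 2 and 1 fragments for SNORD73. For 22 of the 24 loci, which were 63 to 108 bp long, the intervals imply under 10 fragments in every library. The exceptions were an antisense RNA of 647 bp on chromosome 1 (111727037 to 111727683), at 28.3 and 50.0 FPKM in CRYM cells, with 466 and 837 implied fragments, and the pseudogene RP11-299J3.6, with 10 in each empty vector library. No fold is given against a group at 0.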

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

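The test against sequencing depth and the ratios by pairs of libraries were chosen after the counts were seen. The tables hold many assembled loci that are not in all 4 libraries and so entered no comparison, and they were more numerous in the CRYM libraries, with 43801 in CRYM library 1 and 50463 in CRYM library 2, against 36673 and 40224 in the empty vector libraries. CRYM library 1 was the shallowest of the 4, at a relative depth of 0.842, and still had more of them than either empty vector library, which argues against depth as the cause. On the autosomes and X, loci of this kind under 1000 bp made up an excess of 15242 in the CRYM libraries. Of the excess 46.3% lay inside tested loci, where 39.0% and 38.8% of such loci lay in the empty vector libraries. Tested loci cover 19.1% of the genome, a ratio of shares of 2.43 (95% interval 2.31 to 2.55, counting error only). The ratio was 2.24 to 3.11 over the 4 pairs of a CRYM with an empty vector library. This argues against evenly spread genomic DNA as the only source of the excess, but not against a part from it. RNA from within the span of expressed loci, such as introns, could give such a ratio. Short loci of the empty vector libraries also lay there above that share, so the ratio is not particular to the excess. Carry-over of plasmid or a difference in library preparation was not tested, and a biological effect of CRYM stays open as well.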

How the results depend on the processing

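The subsets of loci were chosen after seeing the data. Leaving out any 1 library gave 0 higher and 0 lower calls in each case, and CRYM at 5.0 to 5.15 (limma adjusted p 0.0550 to 0.0713). The lone library is assumed to vary like the other group, and 1 residual degree of freedom is left, so that the 4 fits test with less power by construction. With the replicate block limma also called 0 higher and 0 lower (3819 at an unadjusted p under 0.05), with CRYM at 5.07 and an adjusted p of 0.0569. Deviations of same-numbered libraries correlated at 0.0360 over loci (-0.0250 above 0 in all 4). The main fit was planned without pairs, because the labels do not say that the replicate numbers pair across groups. Without the filter on low FPKM 26476 loci were tested, of which 788 were higher and 1082 lower, and 1 gene list passed. Fry also passed 1 list, in place of 0 with camera. Rescaling to the same total gave 301 higher and 6303 lower, and 73.2% of the main calls kept their direction. It divides by totals that the short assembled loci enter, and makes values smaller against the pseudocount (CRYM at 2.54); the part of each in the shift was not tested. Named loci and CRYM alone gave 155 higher and 143 lower, with 2499 loci tested, where the main fit had 660 calls among these loci. Of the genes named here only CRYM was checked in this setting (limma adjusted p = 0.00967), so which other calls were lost is not given. Loci whose FPKM per implied fragment agreed within 1.1-fold among libraries (2561 tested) gave 496 higher and 199 lower, a share of higher calls of 71.4% where all loci gave 47.0%, and the cause was not tested. The other settings kept both counts within 1.5 times. Of the genes named, 2 without a call changed sign, HSPB1 to 0.000 without CRYM vector replicate 1 (-0.102 to 0.000 without any 1 library) and RPL27 to 0.0380 with quantile normalization, and the cause was not tested. Among 88 named loci with a test, 14 lost the call without the filter, 8 with quantile normalization (JUNB, XBP1, HOXB13, IFIT2 and TFF3 among them) and 6 with rescaling (JUN, BTG2 and IFIT2 among them), while 5 gained one with rescaling (KLF9, HSPB1, RPL27, RPLP1 and HLA-DRA). JUNB also lost it without the trend. At 62 bp 1 read is worth an FPKM of 635.6 to 868.7, so short loci have little precision.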

Other observations

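The genes of this paragraph were chosen after their values were seen, among protein-coding loci of at least 300 bp with no library at 0. ADRA2A, an alpha-2 adrenergic receptor, rose 7.18-fold from 2.19 ± 0.356 to 15.7 ± 0.0664 FPKM (SD, n = 2). SOX9, a transcription factor of progenitor cells, rose 2.74-fold, and the secreted trefoil peptides TFF3 and TFF1 rose 2.81-fold and 3.37-fold. The actin-binding thymosins TMSB4X and TMSB10 rose 2.04-fold and 1.86-fold, with implied fragments at 1.76 and 1.28 times the empty vector level. The metallothionein MT1F rose 1.99-fold. S100P, a calcium-binding protein, fell 3.22-fold from 40.9 ± 2.11 to 12.7 ± 0.968 FPKM. Lower values were also called for ID3 (2.89-fold), the protease inhibitor SLPI (2.42-fold) and the CDK inhibitor CDKN2D (2.19-fold). The GTPase RAC3 fell 2.46-fold, and PEBP1, an inhibitor of RAF kinase, fell 1.97-fold from 449.3 to 227.9 FPKM. The implied fragments of RAC3 and PEBP1 were at 0.613 and 0.652 of the empty vector level, smaller falls than in FPKM. NPPC and the hormone FGF21 fell 8.25-fold and 8.37-fold to 0.310 and 0.202 FPKM. TFF3 and ID3 lost the call without the filter on low FPKM, and TFF3 also with quantile normalization and on rescaling to the same total. MFGE8 was listed 11.6-fold higher over 1139 bp, but its intervals imply fragments at 0.603 of the empty vector level, so its rise in FPKM does not come with more implied reads.

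Families and biotypes were also tested only after the data were seen. Of 16 tested, 4 passed limma camera and 0 with an estimated correlation. Of 9 tested histone genes, measured in polyadenylated RNA only, 7 were higher and 0 lower, among them HIST1H4E (4.18-fold) and HIST1H2AE (3.67-fold). The limma camera adjusted p was 0.00371, and 0.393 with an estimated correlation. The family's median stayed above 0 under each scaling (0.248 to 1.18). Of 250 lincRNA loci 56 were higher and 15 lower, with a camera adjusted p of 0.00658, and 0.393 as the adjusted p with an estimated correlation. Their median log2 difference of 0.171 turned to -0.0650 on rescaling to the same total, a scaling that moved the median of all loci by -0.383. The others that passed were sense-intronic loci (79 tested, 13 higher and 3 lower) and miscellaneous RNA loci (173 tested, 18 and 6). Their limma camera adjusted p was 0.0230 and 0.0285, and 0.393 for each with an estimated correlation. Their medians of 0.165 and 0.265 turned to -0.052 and -0.039 on that rescaling. Among loci without a name, those at chromosome 20 (36531499 to 36573752) and chromosome 1 (120290619 to 120311528) rose 13.9-fold and 5.67-fold, with implied fragments at 12.1 and 2.47 times the empty vector level. The locus at chromosome 6 (17281577 to 17294106) fell 9.76-fold, with implied fragments at 0.180 of that level. The locus at chromosome 10 (90033621 to 90344287) was called lower, at 10.4 and 9.08 FPKM in empty vector cells and 0.313 and 0.109 in CRYM cells, with implied fragments at 0.0404.

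Of the 3 ways to split the 4 libraries into 2 and 2, 1, the real one, gave 3365 calls, and the others gave at most 45. That is too few splits for a share under 0.05. This count was chosen after the result was seen.

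The tests of this paragraph were chosen, and replaced more than once, after the result was seen. UGT2B15 and UGT2B17, which androgen represses, rose, and SPDEF and MAF, which it induces, fell. Rescaling to the same total, which moved the median locus by -0.383, left UGT2B15 at 1.71 and UGT2B17 at 1.39, both still past the limma threshold. Their rises of 3.12 and 2.52 in the main fit were far larger than that shift. Rescaling could therefore hardly have removed them, and its outcome does not test a scaling difference. A factor shared by all loci would also have moved the median locus, which differed by 0.011 in the main fit. With quantile normalization, which moved other loci, SPDEF was at -0.75 and MAF at -0.728, both still past the limma threshold. The median locus moved by -0.002 with it, so there was little of a factor per library to remove. That both falls stayed past the threshold therefore adds little on such a factor. On rescaling to the same total, SPDEF was at -1.255 and MAF at -0.353. For MAF that is no more than the shift of the median locus. MAF, at 4.4 and 2.6 FPKM, lies below the median tested locus, at 11.3 to 11.5 FPKM per library. The pseudocount therefore shrinks its difference more on that scale, and rescaling cannot tell whether its fall stands apart. The fragments implied for SPDEF did not follow depth between the empty vector libraries. Their ratio at equal depth, 0.985, therefore cannot tell whether its reads fell, and the fall rests on the FPKM alone. A biological effect of CRYM on these genes stays open and was not tested.

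The split by implied fragments was chosen after the test of all these loci together. At 154 loci both libraries of one group were listed at 0 and both of the other at 1 or more, 93 at 0 in empty vector and 61 at 0 in CRYM cells, against an average of 105.0 over the 2 crossed pairings of libraries. The 95% Poisson interval of the count, 130.6 to 180.3, lies above that average, though not above 2 times it, the bound set beforehand. Under the rule set beforehand, that average was high enough for zeros scattered at random to account for these loci. Against the average itself, a bound taken after the result was seen, they may account for part of these loci but not for all. Loci with under 10 implied fragments, 73 by group against 93.0, are in line with random zeros. The 81 loci with 10 or more are not, against 12.0 (95% Poisson interval of the count 64.3 to 100.7). Other listed loci over the same bases held more FPKM where the locus was at 0 for 35.7% of the 154, against 24.2% of matched loci, a difference of 0.115 (95% interval 0.0320 to 0.201), with 35 of the 81 deeper ones among them, so reads assigned to an overlapping locus may account for part of them, and a biological difference stays open for the rest.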
